A study of Homo sapiens with 36 samples.

How the data were processed

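Gene expression was measured in monocytes of 26 people with chronic graft-versus-host disease (CGVHD) and 10 unaffected donors (ND), 1 Affymetrix Human Gene 1.0 ST array each. The deposited values were on the log2 scale at probe-set level: 257430 probe sets in 36 arrays, from 1.8 to 14.7, with 0 missing. How the authors summarised, background-corrected and normalized the arrays was not given in the sources used here; array medians lay close together but were not equal. Treatment of the people, dates and batches were not given in the labels and were not analysed here. The labels give separate titles, taken here as separate people, so each array counted as 1 independent sample.

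Probe sets were joined to gene symbols with the platform's annotation, and 2478 older symbols were brought up to date with the RefSeq gene table of GRCh38.p14. Of the probe sets, 224320 carried 1 symbol, 10159 several and 22951 none. A gene's value was the mean of its single-symbol probe sets (median 10 per gene, 1056 genes with 1), which gave 18660 genes after 41 sex-linked symbols were left out. The file held 6573 probe sets with values identical to another's, 2709 of them within the same gene, which were kept. The lowest 25% of genes by mean value were left out, leaving 13995. No column of values was left unused.

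Genes were compared with limma 3.58.1 in R 4.3.3 (linear model with 1 coefficient for the group, moderated by empirical Bayes), with Benjamini-Hochberg adjustment and a threshold of 0.05; every adjusted p of a single gene is from limma. Fold intervals are 95% intervals of that model. Before the data were examined, 28 gene lists were fixed: 14 of functions, 1 of immediate-early genes as a sign of handling, and 13 of cell types, with 452 members, 19 of which had no probe set of their own. Each list was tested against other genes with camera (preset correlation 0.01, and an estimated correlation beside it) and on its own with fry. The score of a list in an array, the mean log2 value of its tested genes, was compared between groups by permutation (100000 resamples), and the ratio of the groups' SDs likewise for the 14 function lists, on values centred on their group medians. Correlations between 6 list scores within CGVHD (15 pairs) used permutation p-values; where the glucocorticoid-responsive score showed a gap, they were computed on each side of it, and the width of the gap relative to the SD was compared, after it had been seen, with 100000 simulated normal draws. List-level p-values were adjusted over all lists or pairs of their family, and the smallest permutation p is 1e-05. The permutation tests of score differences take both groups to spread alike, so p can come out too small where ND spreads more.

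The genes named were fixed by a rule before the data were examined: the 10 largest rises and 8 largest falls in log2 fold change among genes past the threshold with at least 2 probe sets, the 2 members with the smallest p of each function list, and the 1 such member of each other list, passing over uncharacterised loci and receptor or immunoglobulin segments. The rule named 55 genes, of which 44 passed; genes named outside it are said in the text to have been chosen after their values were seen or for their level.

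Alternatives fixed before the data were examined were no filter or a 50% filter on dim genes, quantile normalization, median centring, the median of probe sets, array weights with a variance per group, trended and robust moderation, scores of T, B, NK, mature neutrophil, platelet and erythroid markers as covariates, the title number as a block, rank-sum tests, stricter thresholds and each array left out in turn. Alternatives added after seeing the data were the glucocorticoid-responsive score as covariate, leaving out CGVHD 1, 2 and 11 or the arrays with a T cell score of at least 8, and CGVHD 1 to 10 or 11 to 26 alone. Arrays were also regrouped at random into 99 other splits of the same sizes.

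The gene test was checked on simulated data. With 100 genes changed by 0.5 on the log2 scale it recovered 77%, and with 100 changed by 1 it recovered 100%. There were 9 unchanged genes among 186 calls, and the sign was right in 177. The simulated genes were independent and normal, with the same SD in both groups. The check therefore does not cover correlated genes or groups of unequal spread. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.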

Results

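Circulating monocytes of people with chronic graft-versus-host disease (CGVHD, an immune disorder after transplantation of donor blood stem cells) were profiled beside those of unaffected donors (ND). The data held 36 Affymetrix Human Gene 1.0 ST arrays, 26 of CGVHD and 10 of ND monocytes, with 1 array per title. Monocytes had been sorted from frozen blood mononuclear cells by light scatter and a CD3-negative, CD4-dim gate. Values were log2 signals of probe sets, from 1.81 to 14.71, averaged here into 18660 genes, of which 13995 were bright enough to test. Array medians lay between 7.18 and 7.29 (CGVHD mean 7.24 ± 0.03 SD, n = 26; ND mean 7.24 ± 0.04 SD, n = 10). The number of arrays limits the precision of every value. A list score is the mean log2 value of a list's tested genes in an array, and each ± is an SD unless named otherwise. All tests were two-sided, and each p of a gene or list is adjusted over all genes or lists unless said otherwise.

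In permutation tests of list scores, the sorted cells of CGVHD were higher in interferon-gamma-inducible genes (0.60 on the log2 scale), receptors for microbial and damage signals (0.40) and platelet markers (0.60), and lower in plasmacytoid dendritic cell markers (-0.41). Tested against other genes with an estimated correlation, these 4 lists had adjusted p-values of 0.0690, 0.0690, 0.373 and 0.373. The platelet and plasmacytoid differences also missed the threshold with the glucocorticoid-responsive score as covariate (p = 0.0961 and 0.0667) and with CGVHD 1 to 10 alone (p = 0.194 and 0.10). Type I interferon-inducible genes scored 0.46 higher without passing (adjusted permutation p = 0.0702). The 2 interferon lists were not tested against each other. CXCL10, a chemokine that draws activated T cells, was 3.35-fold higher in CGVHD (95% interval 2.14 to 5.26, n = 26 against 10), with log2 means of 9.40 ± 0.91 and 7.65 ± 0.88. FPR2, a receptor for formylated peptides and other danger signals, was 2.46-fold higher (1.87 to 3.24) and lay above the ND mean in 26 of 26 CGVHD arrays. CLEC4C, a surface lectin of plasmacytoid dendritic cells, fell by 0.91 on the log2 scale and lay below the ND mean in 25 of 26. The comparison addresses the question posed by the series, whether gene expression of circulating monocytes carries a record of systemic cytokines in this disease.

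Across the 13995 genes tested with limma, 1199 passed an adjusted p of 0.05, of which 545 rose and 654 fell in CGVHD. With each array centred on its median, 658 rose and 512 fell, so which direction held more genes depended on the scaling. Changes of at least 1.5-fold were mostly rises, 134 of 186, as were those of at least 2-fold, 27 of 34. The median log2 change over all tested genes was -0.02. Without ND 2, 553 genes passed (229 up, 324 down), and without ND 7, 650 (283 up, 367 down). Without ND 9, 344 genes rose.

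The 10 largest rises ran from 2.56-fold to 4.26-fold. IL1R2, a decoy receptor that binds interleukin-1 without signalling, rose 4.26-fold (95% interval 1.89 to 9.61, adjusted p = 0.0207, 23 of 26 CGVHD arrays above the ND mean), with log2 means of 9.56 ± 1.89 and 7.47 ± 0.47. CXCL10 had an adjusted p of 0.0013 (25 of 26). ANKRD22, an ankyrin-repeat gene induced by interferon-gamma, rose 3.23-fold (2.19 to 4.78, p = 0.00078, 26 of 26). TNFAIP6, whose product binds hyaluronan and dampens inflammation, rose 2.99-fold (1.81 to 4.94, p = 0.0066, 24 of 26). CCR2, the receptor by which classical monocytes leave the marrow and enter tissue, rose 2.58-fold (1.74 to 3.82, p = 0.0029, 26 of 26). CD163, the haemoglobin scavenger receptor, rose 2.56-fold (1.53 to 4.28, p = 0.0182, 23 of 26). The stress chaperones HSPB1 and HSPA6 rose 2.57-fold (1.58 to 4.18, p = 0.0126) and 3.53-fold (1.53 to 8.15, p = 0.0491). SLC1A3, a glutamate transporter, and TPST1, a tyrosine sulphotransferase, rose 2.73-fold (p = 0.028) and 2.66-fold (p = 0.0362). With the glucocorticoid-responsive score as covariate, 5 of the 10 no longer passed, with log2 differences going from 2.09 to 0.71 for IL1R2, itself in that list (p = 0.0717), 1.35 to 0.52 for CD163 (p = 0.0855), 1.45 to 0.43 for SLC1A3 (p = 0.114), 1.41 to 0.41 for TPST1 (p = 0.222) and 1.82 to 1.54 for HSPA6 (p = 0.114). With 6 marker scores as covariates IL1R2 (1.36), CD163 (0.95), SLC1A3 (1.12), TPST1 (0.80), HSPA6 (1.19), TNFAIP6 (1.58 to 0.87, p = 0.223) and HSPB1 (1.36 to 1.20, p = 0.0891) did not pass, while CXCL10, ANKRD22 and CCR2 did.

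Among the 8 largest falls, 6 passed with the glucocorticoid-responsive score as covariate and 5 with 6 marker scores. PMP22, a tetraspan membrane protein, fell by 1.23 on the log2 scale, making it 2.35-fold higher in ND (adjusted p = 0.00084, 25 of 26 CGVHD arrays below the ND mean). SMAD7, an inhibitor of transforming growth factor beta signalling, fell by 1.23 as well (p = 0.0020, 25 of 26), with log2 means of 6.92 ± 0.60 and 8.15 ± 0.84. DPP4, a peptidase on T cells that trims chemokines, fell by 1.17 (p = 0.037, 24 of 26). FCER1A, the alpha chain of the IgE receptor on dendritic cells and basophils, fell by 1.05 (p = 0.0228, 24 of 26). LGMN, a lysosomal protease of antigen processing, fell by 0.96 (p = 0.0013, 26 of 26), and UGCG, which makes glucosylceramide, fell by 0.97 (p = 0.0053). FHIP1A fell by 1.07 (p = 0.0012), and ITM2C, an integral membrane protein, fell by 1.00 (p = 0.0084). ND 8 was the highest ND array for LGMN, UGCG, FHIP1A, ITM2C and FCER1A, though not for PMP22, SMAD7 or DPP4. It also had the highest plasmacytoid and conventional dendritic cell marker scores of all arrays (8.50 and 8.96). Whether dendritic cell content accounts for these falls was not tested. The falls that ended were FCER1A (-0.58, p = 0.137) and DPP4 (-0.90, p = 0.116) with the glucocorticoid score, and FCER1A (-0.43, p = 0.458), DPP4 (-0.80, p = 0.0845) and ITM2C (-0.73, p = 0.0829) with the marker scores. In GRCh38.p14, CXCL10 lies on chromosome 4 from 76021118 to 76023497, FPR2 on chromosome 19 from 51761180 to 51770531, IL1R2 on chromosome 2 from 101991960 to 102028544 and SMAD7 on chromosome 18 from 48919853 to 48950965.

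Of these 18 genes, 11 passed whichever single array was left out. CD163 and IL1R2 missed without ND 2 (adjusted p = 0.0556 and 0.0524), SLC1A3 without ND 2 or ND 7 (highest 0.0567), FCER1A without ND 7 or ND 8 (highest 0.0603), TPST1 without ND 3, 6, 7, 8 or 9 (highest 0.0585), DPP4 without ND 3, 4, 5, 7, 8 or 10 (highest 0.0815), and HSPA6 passed in 14 of 36 such fits (highest 0.0998). Of the genes named below for their lists, EDEM1 missed without ND 2 (0.0505), CXCR2 without ND 2 or 7 (highest 0.0572), CD38 without ND 2, 7 or 9 (highest 0.0813), FKBP5 without ND 2, 3, 7 or 9 (highest 0.0603), ATF4 without ND 2, 6, 7, 8 or 9 (highest 0.0858), HLA-DMA without ND 1, 2, 7, 8 or 9 (highest 0.0998), and ANXA1 without ND 1, 2, 3, 5 or 8 or CGVHD 11 or 24 (highest 0.103). PRDX1 passed in 24 of the 36 fits (highest 0.151), HMGB2 in 22 (0.0997), DDB2 in 16 (0.132) and CKB in 13 (0.138). Among these list genes, the glucocorticoid covariate moved IL10 from 1.25 to 0.68 (p = 0.0435, still passing), VSIG4 from 1.34 to 0.63 (p = 0.0923), HMGB2 from 0.58 to 0.22 (p = 0.274) and HLA-DMA from -0.29 to -0.18 (p = 0.163). FKBP5 went from 1.07 to 0.34 (p = 0.162), but as a member of the covariate's own list its shrinkage is partly built in. This covariate also ended the calls of ANXA1 (0.15 to 0.14), CKB (-0.40 to -0.35), DDB2 (0.39 to 0.33), ITGB3 (1.18 to 0.95) and EDEM1 (-0.32 to -0.24), whose differences changed less. The marker scores moved IL10 from 1.25 to 0.82 (p = 0.126) and CLEC4E from 1.27 to 0.84 (p = 0.0852), and ended 14 further calls besides ITGB3 (1.18 to 0.16, p = 0.411). Of these, HMGB2 went from 0.58 to 0.32 and HLA-DMA from -0.29 to -0.14, while smaller drops were seen for CLEC4C (-0.91 to -0.78, p = 0.0914), VSIG4 (1.34 to 0.92), FKBP5 (1.07 to 0.92), ME1 (0.67 to 0.50), NDUFB3 (0.53 to 0.48), CXCR2 (0.53 to 0.42), CKB (-0.40 to -0.34), EDEM1 (-0.32 to -0.25) and ANXA1 (0.15 to 0.13). ITGB3 and CXCR2 are themselves in the platelet and mature neutrophil scores, so their shrinkage with those covariates is partly built in too. The differences of CD38 (0.64 to 0.72), PRDX1 (0.33 to 0.38) and ATF4 (-0.28 to -0.34) were larger with the marker scores, although their calls ended too, so a lost call alone does not show that other cells account for a change.

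**Figure D1:**
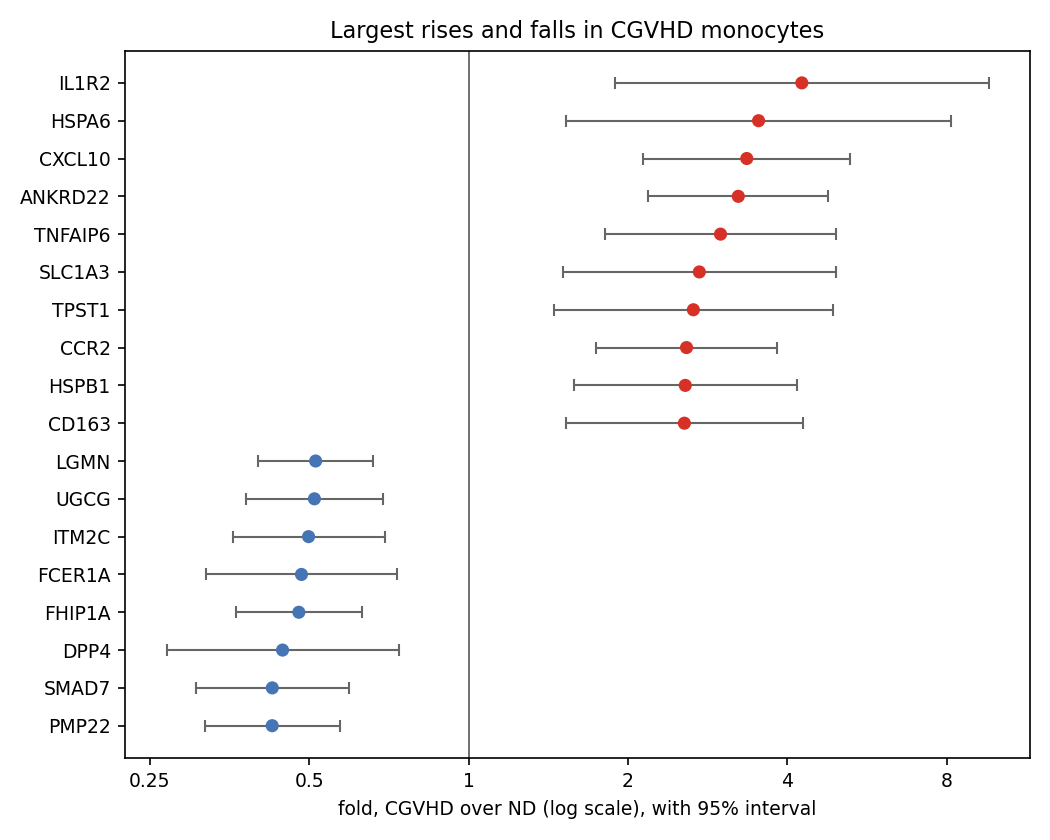
Fold of CGVHD (n = 26 arrays) over ND (n = 10) on a log scale for the 10 largest rises (red) and the 8 largest falls (blue), with 95% intervals; the line marks no difference. IL1R2 rose most, 4.26-fold, with a wide interval from 1.89 to 9.61, and PMP22 and SMAD7 fell most.

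Interferon-gamma-inducible genes rose as a group. Their score was 9.13 ± 0.33 in CGVHD (n = 26) and 8.53 ± 0.25 in ND (n = 10), a difference of 0.60 on the log2 scale (SE 0.10), with 26 of 26 CGVHD arrays above the ND mean and 16 above the highest ND array. The permutation test gave an adjusted p of 0.00056 over 28 lists. Of 19 tested members, 12 rose, 0 fell and 7 did not pass; adjusted over the list alone, 14 rose. They included the chemokines CXCL10 and CXCL11 (1.95-fold, adjusted p = 0.0003), the antimicrobial GTPases GBP1 (2.43-fold) and GBP5 (2.16-fold), and SERPING1, an inhibitor of complement C1 (2.11-fold); the GBP genes and SERPING1 were picked after their values were seen. Against the other genes, camera with its preset correlation gave an adjusted p of 2.1e-12, and with an estimated correlation the adjusted p was 0.0690.

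In type I interferon-inducible genes, the antiviral set, all 38 tested members were higher in the CGVHD mean, and 9 rose, among them PARP9, a partner of DTX3L in interferon responses (1.74-fold, adjusted p = 0.0035), and RIGI, the cytosolic sensor of viral RNA (1.77-fold, p = 0.0122); adjusted over the list alone, 16 rose. The score was 8.68 ± 0.57 in CGVHD and 8.22 ± 0.41 in ND, and its difference of 0.46 (SE 0.17) missed the threshold, with an adjusted permutation p of 0.0702 and 21 of 26 CGVHD arrays above the ND mean. It passed without ND 10 (0.539) or without CGVHD 16 (0.491), and was 0.279 (p = 0.194) with CGVHD 1 to 10 alone. The camera adjusted p was 1.5e-11, and 0.378 with an estimated correlation. The difference of 0.46 here was not tested against the 0.60 of the interferon-gamma list. These 2 lists therefore do not tell which interferon accounts for either difference.

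Genes of MHC class I antigen processing, which load peptides for CD8 T cells, were 0.12 higher (SE 0.04, adjusted permutation p = 0.0583, 20 of 26 above the ND mean). Of 18 tested, 3 rose, also adjusted over the list alone: the peptide transporter TAP1 (1.44-fold, adjusted p = 0.0065), the proteasome activator PSME2 (1.43-fold, p = 0.0123) and PSMB9, the last chosen after its value was seen (1.33-fold, p = 0.0487). Camera gave an adjusted p of 0.0087, and 0.378 with an estimated correlation. The score passed with arrays centred on their medians (0.131, p = 0.0201) and under 5 other alternatives. For MHC class II and costimulation, HLA-DMA, which helps load class II peptides, fell by 0.29 (p = 0.0369), as 1 of 15 tested, also adjusted over the list alone, while HLA-DOA differed by -0.38 without passing (p = 0.16). That score differed by -0.03 (adjusted permutation p = 0.879; camera adjusted p = 0.783).

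Receptors for pathogen and damage signals formed the second group that rose. Their score was 9.42 ± 0.17 in CGVHD and 9.02 ± 0.27 in ND, a difference of 0.40 (SE 0.09, adjusted permutation p = 0.00056), with 25 of 26 CGVHD arrays above the ND mean and 14 above the highest ND array. Of 29 tested, 10 rose and 1 fell; adjusted over the list alone, 15 rose and 2 fell. FPR2 had an adjusted p of 0.00028. CLEC4E, which senses dead cells and mycobacterial glycolipid, rose 2.40-fold (p = 0.0018, 26 of 26), and TLR4, the endotoxin receptor, and NLRC4, an inflammasome sensor, both named after their values were seen, rose 1.46-fold (p = 0.0020) and 1.96-fold (p = 0.0021). AGER, the receptor for advanced glycation products and HMGB1, named after its value was seen, was the 1 member that fell, by 0.31. The camera adjusted p was 1.2e-09, and 0.0690 with an estimated correlation.

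Alarmins, proteins that signal damage once released, scored 0.29 higher (SE 0.08, adjusted permutation p = 0.0198, 23 of 26 above the ND mean). The median member was 0.19 higher, and the member HSPA1B, picked after its value was seen, was 1.65 higher without passing (limma adjusted p = 0.0530). HMGB2, a chromatin protein, rose by 0.58 on the log2 scale (adjusted p = 0.0412) and ANXA1, a glucocorticoid-inducible resolver of inflammation, rose 1.11-fold (p = 0.0399), the 2 of 13 that passed; adjusted over the list alone, 7 rose and 1 fell. By camera the adjusted p was 0.0049, and 0.373 with an estimated correlation. The score missed the threshold without ND 8 (0.254, p = 0.0629), with CGVHD 1 to 10 alone (0.288, p = 0.0822), without arrays of high T cell score (0.270, p = 0.139) and with the glucocorticoid score as covariate (0.235, p = 0.104). With 6 marker scores as covariates the difference itself dropped to 0.149 (p = 0.333).

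Scavenger, repair and matrix genes scored 8.78 ± 0.25 in CGVHD and 8.48 ± 0.22 in ND, a rise of 0.30 (SE 0.08, adjusted permutation p = 0.0139, 22 of 26). The 3 of 19 that rose, also adjusted over the list alone, were all scavenger or complement receptors of macrophages: MSR1 (2.09-fold, p = 0.0018), VSIG4 (2.53-fold, p = 0.0156) and CD163. None of its tested matrix genes passed. By camera the adjusted p was 0.0168, and 0.373 with an estimated correlation. The score was 0.134 with the glucocorticoid-responsive score as covariate and 0.196 with 6 marker scores as covariates, and did not pass with either, nor with CGVHD 1 to 10 alone (0.235, p = 0.0640).

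Glucocorticoid-responsive genes differed between the people with CGVHD more than between ND donors. The score was 9.81 ± 0.64 in CGVHD and 9.29 ± 0.22 in ND, and the SD ratio of 2.99 passed its permutation test (adjusted p = 0.0347), the only 1 of 14 function lists to do so. The spread missed the threshold in 20 of the 36 fits with 1 array left out. Scores in CGVHD fell on both sides of a gap from 9.57 to 9.94, with 14 arrays below and 12 above. The 12 above it also exceeded the highest ND array at 9.69. The difference in means of 0.52 (SE 0.14) had an adjusted permutation p of 0.0583, and with 6 marker scores as covariates it was 0.299 (p = 0.338). Of 19 tested, IL1R2 and FKBP5, a co-chaperone of the glucocorticoid receptor (2.10-fold, adjusted p = 0.0296), rose; adjusted over the list alone, 6 rose. Against other genes camera gave an adjusted p of 6.1e-06, and 0.378 with an estimated correlation.

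Inflammatory cytokines and NF-kB targets scored 0.28 higher without passing (adjusted permutation p = 0.305). TNFAIP6 and IL10, an anti-inflammatory cytokine (2.38-fold, adjusted p = 0.0088), were the 2 of 21 that rose, also adjusted over the list alone. The camera adjusted p was 0.0087, and 0.547 with an estimated correlation; with CGVHD 1 to 10 alone the list leaned downward (adjusted p = 0.774), and with CGVHD 11 to 26 alone its score passed (0.493, p = 0.0435).

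The other fixed lists of stress and growth programmes did not pass as groups. In the unfolded protein response, EDEM1, which sends misfolded glycoproteins to degradation, and ATF4, its transcription factor, fell by 0.32 (adjusted p = 0.0189) and 0.28 (p = 0.0362), the 2 of 15 that passed, also adjusted over the list alone; the score differed by 0.01 (p = 0.879). In the oxidative stress response, malic enzyme ME1 and peroxiredoxin PRDX1 rose 1.59-fold (p = 0.0112) and 1.26-fold (p = 0.0418), 2 of 15, with 2 up and 1 down adjusted over the list alone; the score differed by 0.04 (p = 0.653). In the p53 response, the death receptor FAS and the repair gene DDB2 rose 1.53-fold (p = 0.0042) and 1.31-fold (p = 0.0449), 2 of 19, also adjusted over the list alone; the score differed by 0.07 (p = 0.226), while the median member was at -0.0039. NDUFB3, a complex I subunit, rose 1.44-fold (p = 0.0091), as 1 of 19 oxidative phosphorylation genes, also adjusted over the list alone, while SDHA of complex II differed by -0.14 (p = 0.0802) and the score by less than 0.01 (p = 0.961). Of 10 proliferation genes 0 passed, also adjusted over the list alone; PCNA was at 1.30-fold (p = 0.0744), MCM3 at 1.24-fold (p = 0.172) and the score at 0.12 (p = 0.146). Immediate-early genes, which respond to handling of cells, had 0 of 15 passing, also adjusted over the list alone; FOS was at 1.11-fold (p = 0.327) and the score at -0.06 (p = 0.868), while camera pointed upward. The camera adjusted p-values of these 6 lists were 0.890, 0.331, 0.162, 0.845, 0.105 and 0.940, in the order named.

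**Figure D2:**
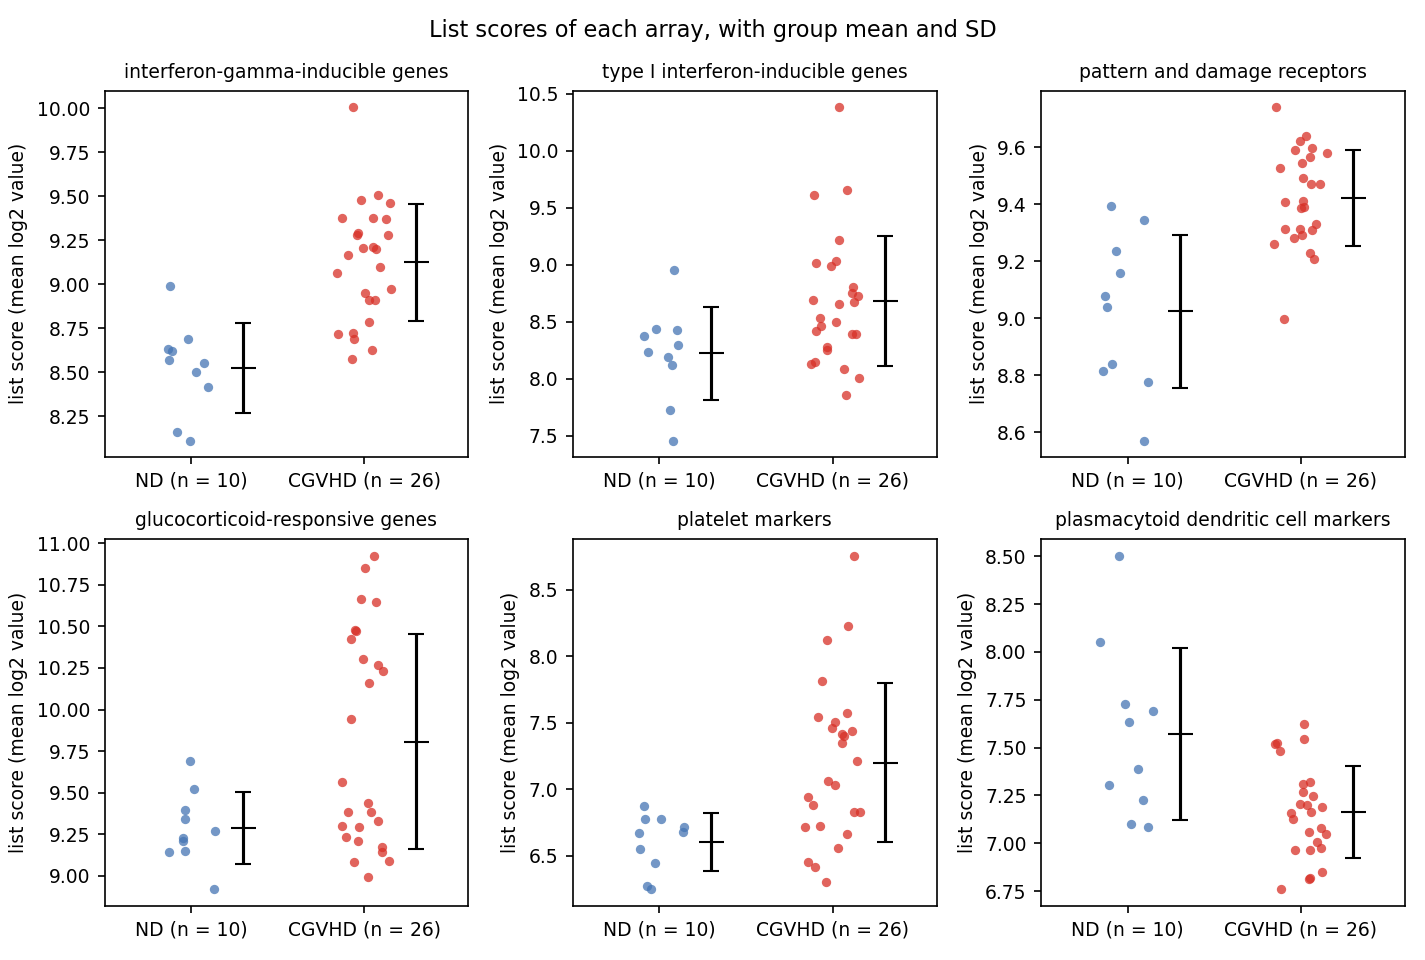
List score of each array (dots, mean log2 value of a list's tested genes) for 6 lists in ND (blue, n = 10) and CGVHD (red, n = 26), with bars for group mean and SD. Interferon-gamma-inducible scores of 16 CGVHD arrays lie above every ND array, glucocorticoid-responsive scores in CGVHD leave a gap between 9.57 and 9.94, and plasmacytoid dendritic cell scores lie lower in CGVHD.

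Marker lists of other blood cells were tested too. The light-scatter gate may remove free platelets and most plasmacytoid dendritic cells, but what it removed was not tested. Plasmacytoid dendritic cell markers fell, with scores of 7.16 ± 0.24 in CGVHD and 7.57 ± 0.45 in ND, a difference of -0.41 (SE 0.15, adjusted permutation p = 0.0111, 25 of 26 CGVHD arrays below the ND mean). ND spread more, so this permutation p is likely too small. ND 8 was the highest of all arrays at 8.50. With 1 array left out the difference lay between -0.463 and -0.305 (highest adjusted permutation p 0.0394). CLEC4C (adjusted p = 0.0076) and LILRA4, an inhibitory receptor of the same cells named after its value was seen (-0.64, p = 0.0166), were the 2 of 6 that fell, also adjusted over the list alone; the camera adjusted p was 0.0095, and 0.373 with an estimated correlation. The fall missed the threshold with CGVHD 1 to 10 alone (-0.376, p = 0.10) and with the glucocorticoid score as covariate (-0.314, p = 0.0667). Platelet markers were higher by 0.60 (SE 0.14, 7.20 ± 0.60 against 6.60 ± 0.22, adjusted permutation p = 0.0198, 22 of 26), with all 12 tested members higher, 5 rising and 10 adjusted over the list alone. ITGB3, the platelet fibrinogen receptor's beta chain, rose 2.27-fold (p = 0.0253) and PPBP, a platelet granule chemokine chosen after its value was seen, rose 2.51-fold (p = 0.0317). The platelet camera adjusted p was 1.3e-06, and 0.373 with an estimated correlation; the score missed the threshold with arrays of high T cell score left out (0.474, p = 0.202), with CGVHD 1 to 10 alone (0.373, p = 0.194) and with the glucocorticoid score as covariate (0.511, p = 0.0961).

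Classical monocyte markers scored 0.23 higher (SE 0.09, adjusted permutation p = 0.0283, 22 of 26), with CCR2 and RNASE2, an eosinophil and monocyte ribonuclease (1.70-fold, p = 0.0169, named after its value was seen), the 2 of 12 that rose and 3 adjusted over the list alone. The median member was only 0.08 higher, and 9 of 12 were higher in the CGVHD mean. ND spread somewhat more in this score (SD 0.26 against 0.20), so the permutation p may be too small. The camera adjusted p was 0.0367, and 0.483 with an estimated correlation; the score missed without ND 2 (0.217), ND 3 (0.213) or ND 8 (0.164), with CGVHD 11 to 26 alone (0.171), and with 6 marker scores (0.176) or the glucocorticoid score (0.203) as covariates. Non-classical markers differed by -0.09 (p = 0.597); CKB, a creatine kinase, fell by 0.40 (p = 0.0473), as 1 of 14, with 0 adjusted over the list alone. In conventional dendritic cell markers FCER1A and the lipid-presenting CD1E (-0.59, p = 0.03, named after its value was seen) fell, 2 of 7, also adjusted over the list alone, and the score differed by -0.28 (p = 0.0702); it passed without ND 2 or ND 6. Camera gave adjusted p-values of 0.141 and 0.105 for these last lists.

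T cell markers were present at widely differing levels despite the CD3-negative gate, 7.07 ± 0.92 in CGVHD and 7.30 ± 1.31 in ND. Their difference of -0.23 did not pass (adjusted permutation p = 0.731), and CD5, a T and B cell surface protein, differed by -0.72 (p = 0.120), with 0 of 14 members passing. NK cell markers differed by 0.31 (p = 0.379), with the adhesion molecule NCAM1 at 1.36-fold (p = 0.123) and 0 of 11 passing. For B cells the difference was -0.09 (p = 0.879), with the scaffold BANK1 at 1.25-fold (p = 0.554) and 0 of 8 passing. Erythroid markers differed by 0.36 (p = 0.146), with beta-globin HBB at 3.01-fold (p = 0.107) and 0 of 5 passing. Neutrophil precursor genes differed by 0.01 (p = 0.879), with lipocalin LCN2 at 1.18-fold (p = 0.0884) and 0 of 8 passing. Basophil and eosinophil markers differed by -0.02 (p = 0.868), with SIGLEC8 at 1.07-fold (p = 0.189) and 0 of 3 passing. Adjusted over the list alone, 0 passed in each of these 6 lists. In plasma cell markers CD38, an activation-induced ectoenzyme, rose 1.56-fold (p = 0.0279), 1 of 4, also adjusted over the list alone, and the score differed by -0.15 (p = 0.704). In mature neutrophil markers the chemokine receptor CXCR2 rose 1.45-fold (p = 0.0176), 1 of 6 and 2 adjusted over the list alone, and the score differed by 0.19 (p = 0.129). Camera adjusted p-values were 0.496 for T, 0.0942 for NK, 0.940 for B, 0.296 for erythroid, 0.901 for neutrophil precursor, 0.901 for basophil, 0.714 for plasma cell and 0.101 for mature neutrophil markers.

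Over the 28 lists, 7 score differences passed the permutation test, 11 at an unadjusted p under 0.05. Camera with its preset correlation called 10 lists higher and 1 lower; with an estimated correlation it called 0, with 2 at an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance one way, called 4: interferon-gamma-inducible genes (0.00045), pattern and damage receptors (0.00053), plasmacytoid dendritic cell markers (0.0165) and platelet markers (0.0436). Besides the p53 and immediate-early lists, signs differed between median, mean and camera for B cell, plasma cell, neutrophil precursor and basophil markers, none of which passed.

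**Figure D3:**
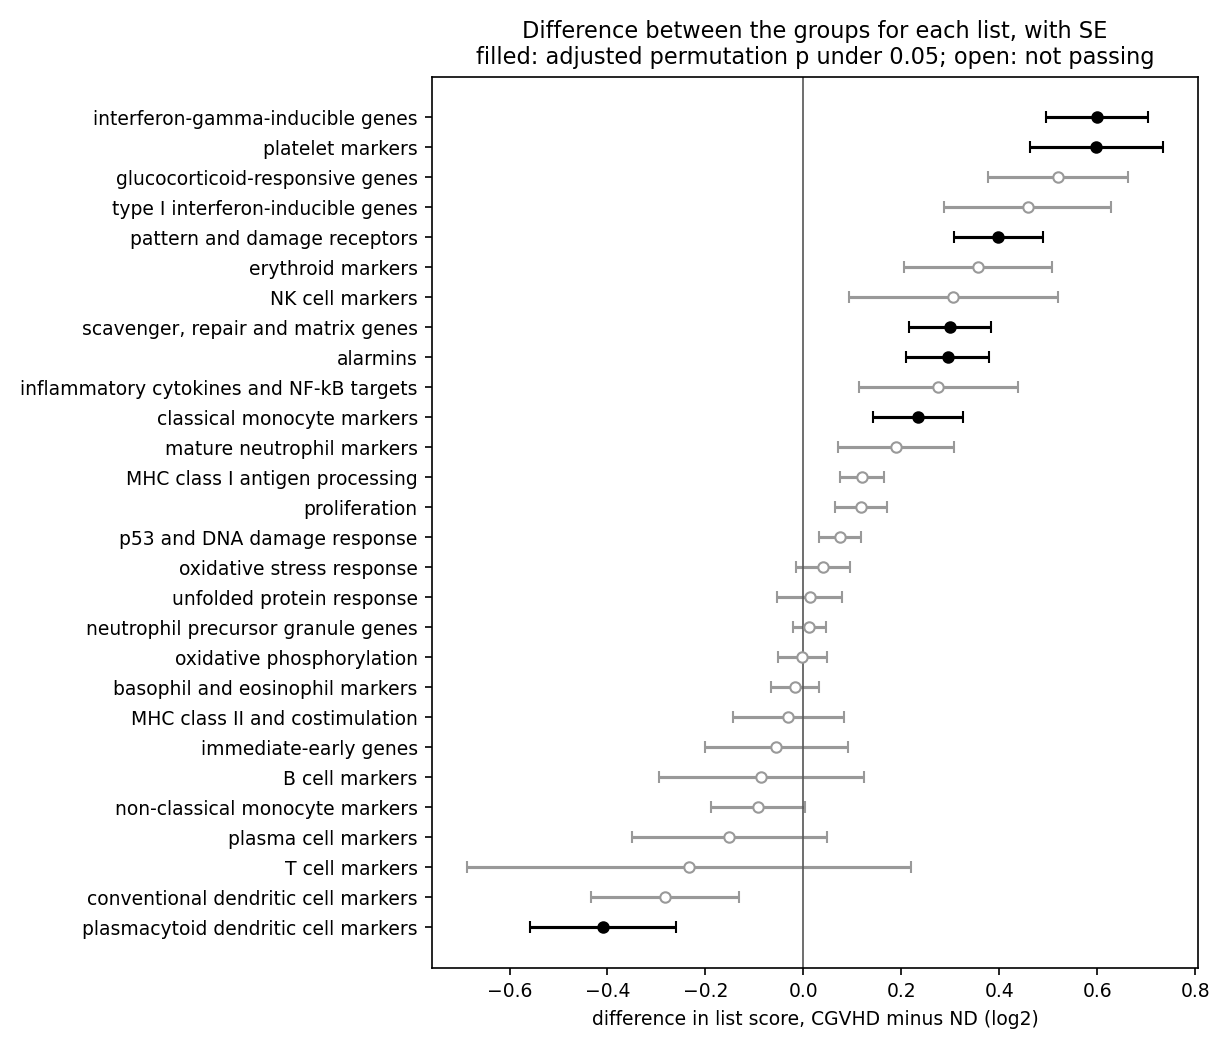
Difference in list score between CGVHD (n = 26) and ND (n = 10) on the log2 scale for 28 lists, with SE; filled points passed the permutation test after adjustment, open points did not. The 7 that passed are 6 higher lists, led by interferon-gamma-inducible genes and platelet markers at 0.60, and 1 lower list, plasmacytoid dendritic cell markers at -0.41.

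Among the people with CGVHD, interferon-gamma-inducible and MHC class I genes varied together. Over 26 arrays the interferon-gamma and MHC class I scores had r = 0.89 (adjusted permutation p = 0.00015) and rho = 0.84 (adjusted p = 0.00015), both with the smallest p that the permutations can give, 1e-05. Without the 2 arrays farthest from the median, r was 0.83. Type I and interferon-gamma scores had r = 0.62 (p = 0.00063, adjusted 0.0047) and rho = 0.49 (p = 0.0111, adjusted 0.0835), and r = 0.45 without the 2 farthest arrays. Interferon-gamma and pattern receptor scores had r = 0.46 (adjusted p = 0.0650) and rho = 0.45 (adjusted p = 0.115). Of 15 pairs computed, the 5 with the glucocorticoid list did not pass over all 26 arrays (lowest adjusted p 0.441 on r and 0.456 on rho), and their r is given only on each side of its gap. Among the other 10 pairs, 2 passed on r. With single arrays left out the number ranged from 1 to 4. Without CGVHD 4 or CGVHD 11 it was 4, and without CGVHD 13 it was 1.

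Relations of the other list scores with the glucocorticoid score were computed on each side of its gap, a split chosen after the scores were seen. A gap as wide relative to the SD arose in simulated draws from 1 normal distribution with p = 0.0339, so separate clusters are only weakly supported. For pattern and damage receptors, in the 14 arrays below the gap r was -0.88 (permutation p = 5e-05, adjusted 0.0005 over 10 relations) and rho was -0.86 (adjusted p = 0.0019). In the 12 above it r was -0.19 (adjusted p = 0.756) and rho -0.24; the difference between the sides was not tested. Over all 26 arrays this pair did not pass (adjusted p = 0.663 on r and 0.859 on rho). The other 8 relations did not pass on r, but 3 passed on rho. These were interferon-gamma-inducible genes below the gap (r = -0.62, adjusted p = 0.0614; rho = -0.66, adjusted p = 0.0453), type I genes above it (r = 0.67, adjusted p = 0.0614; rho = 0.68, adjusted p = 0.0453) and MHC class I genes below it (r = -0.57, adjusted p = 0.0843; rho = -0.65, adjusted p = 0.0453).

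Arrays also differed in ways the groups do not explain. Principal components took 19.7, 12.6, 10.5 and 8.0% of the variance; CGVHD and ND differed on the second (permutation p = 0.00015) and the first (p = 0.0339). On the first component, ND 2 (44.2), ND 9 (37.2), ND 7 (33.5) and CGVHD 16 (32.7) lay highest, and the next array was at 14.6. At its other end CGVHD 1 was at -32.8. Leaving out ND 2, ND 7 or ND 9 gave the lowest gene counts of the single-array fits (553, 650 and 893). Leaving out CGVHD 16 gave the highest (1536). Arrays CGVHD 1, 2 and 11 stood apart on the third component. CGVHD 11 to 26 differed from CGVHD 1 to 10 on the fourth (p = 9.0e-05) and in 184 genes, 149 of them higher. T cell markers were 7.57 ± 0.79 (n = 16) against 6.27 ± 0.43 (n = 10), a difference of 1.30 (adjusted permutation p = 0.0036), NK markers differed by 0.95 (p = 0.0062), and unfolded protein response genes by 0.18 (p = 0.0466). The labels give no batch. Against all ND, CGVHD 1 to 10 gave 451 genes and CGVHD 11 to 26 gave 607. The interferon-gamma score rose by 0.577 with CGVHD 1 to 10 alone and by 0.613 with CGVHD 11 to 26 alone, and the pattern receptor score by 0.463 and 0.357.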

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

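The tests that adjust list scores for covariates were chosen after the results were seen; those on random splits and on further plasmacytoid dendritic cell genes were written down before.

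Interferon-gamma-inducible genes were 0.60 higher in CGVHD monocytes (26 of 26 arrays above the ND mean). The tables argue against variation along the glucocorticoid-responsive genes as the whole cause, since with that score as covariate the difference was 0.636 (SE 0.128, adjusted permutation p = 0.00054). They argue in the same way against other cells in the sorted fraction, as far as 6 marker scores follow these, with 0.725 (SE 0.147, p = 0.00022). A response to interferon in CGVHD, infection and treatment stay open as untested explanations, as does a batch that follows the groups, since the labels give none.

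Plasmacytoid dendritic cell markers fell by 0.41 in CGVHD. T, B, NK, mature neutrophil, platelet and erythroid cells alone are argued against, as far as 6 marker scores follow these. With those scores as covariates the fall was -0.359 (SE 0.135, adjusted permutation p = 0.0305), against -0.409 without them (SE 0.116 in the same kind of model). No dendritic cell score was among the covariates, so they cannot speak to the number of dendritic cells. Fewer such cells among those sorted may account for it, although the support is weak. The 15 tested further genes of this cell type, listed before their values were seen, scored -0.246 (SE 0.123, unadjusted permutation p = 0.0060, 0.0101 adjusted over 5 lists). Of these, 13 were lower and 5 fell (CUX2, SMPD3, DERL3, EPHB1, RUNX2, named after their values were seen). ND spread more than CGVHD in this score (SD 0.377 against 0.154), so the permutation p is likely too small. The margin of about 2 SE leaves both the fall and its size uncertain. The high-scatter gate may remove most plasmacytoid dendritic cells, which are smaller than monocytes, but this was not tested. The most abundant of their listed genes, TCF4 and IL3RA, picked for their level, had log2 means of 8.96 and 7.67 in CGVHD against 9.27 and 7.98 in ND. With the glucocorticoid score as covariate the difference was -0.314 (SE 0.120), 76.8% of its size and 2.61 SE against 3.54 SE without it; the unadjusted permutation p of 0.0099 no longer passed after adjustment over the lists (0.0667), so whether variation along those genes accounts for the fall stays open, with treatment unknown.

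Scavenger, repair and matrix genes rose by 0.30 in CGVHD (SE 0.0888 in the model without covariates). The median member was only 0.14 higher, and 12 of 19 were higher in the CGVHD mean, so this mean leans on CD163, VSIG4 and MSR1. With the glucocorticoid score as covariate the difference was 0.134 (SE 0.065) and no longer passed (adjusted permutation p = 0.120) because the difference shrank, and with 6 marker scores it was 0.196 (SE 0.095, p = 0.103), 65.3% of its size, at 2.06 SE against 3.37 SE without them. CD163, a member, is known to be induced by glucocorticoids. Neither variation along glucocorticoid-responsive genes nor other cells in the fraction can be told apart from CGVHD for this list, since covariates also varied with the group. The glucocorticoid score was 0.52 higher in CGVHD, just short of the threshold (adjusted permutation p = 0.0583), and the platelet score 0.60 higher.

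Among 100 splits of the 36 arrays, 1, the real one, gave as many genes as the observed 1199. The highest of the others gave 353 and 7 gave any. Chance is therefore an unlikely source of the gene count, although 100 splits cannot put its probability below 1 in 100. For the 11 lists called by camera, 11 of the 100 splits gave as many (highest other 17), so chance cannot be excluded for that count; the list results therefore rest on the permutation tests of scores.

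In 8 of 83 sets of values, 1 ND array lay far from the other ND arrays. Of simulated independent normal groups, 4.97% did. The 83 sets share the same 10 arrays and some genes, such as HBB in the erythroid score. These 2 rates therefore do not show an excess over chance. The 26 CGVHD arrays were not examined in this way. ND 9 had a plasma cell marker score of 6.66 (others 7.56 to 8.40), an erythroid marker score of 6.78 (others 5.62 to 6.04), and log2 values of 9.05 for HBB (others 4.91 to 6.20) and 7.87 for HSPA6 (others 5.44 to 6.43). ND 8 had a classical monocyte marker score of 9.75 (others 10.19 to 10.60) and a log2 value of 8.94 for FHIP1A (others 6.34 to 7.53). ND 2 had 7.28 for TPST1 (others 5.76 to 6.50), and ND 1 had 10.64 for ATF4 (others 11.08 to 11.52). Outside the genes compared, 157 of 9785 probe sets with several symbols passed (96 higher, 61 lower in CGVHD), as did 302 of 22951 without a symbol (109 higher, 193 lower).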

How the results depend on the processing

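The alternatives that use the glucocorticoid score, CGVHD 1 to 10 or 11 to 26 alone, the 3 arrays apart or arrays with high T cell scores were chosen after the data were seen. The cause was not tested for any change given here unless fewer arrays or a stricter threshold made it.

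Interferon-gamma-inducible genes and pattern and damage receptors kept their rise and passed in the score test under all 11 alternatives (0.566 to 0.725 and 0.357 to 0.463; highest adjusted p 0.0081 and 0.0063) and without any 1 array. The 1199 genes called kept their direction in every alternative limma fit that tested them, apart from the median of probe sets. With that median, 1186 were tested and kept it. How many of the rest were left out by that fit's own filter, rather than reversed, was not counted. Counts within 1.5 times were 1100 without a filter, 1101 with the 50% filter, 1288 with quantile normalization, 1170 with centring, 940 with the median of probe sets, 809 with array weights, 1159 with trended moderation, 1368 with the glucocorticoid covariate, 1158 without the arrays apart and 1432 with high T cell scores left out (21 against 6 arrays). Similar counts did not mean the same genes. Of the 1199, 723 passed again with the median of probe sets and 809 with array weights. With high T cell scores left out 821 did, and with the glucocorticoid covariate 837. In the other fits just listed, between 967 and 1155 did. Genes passing fell to 393 with 6 marker scores (237 higher, 156 lower), to 451 with CGVHD 1 to 10 (238, 213), to 607 with CGVHD 11 to 26 (252, 355), to 186 at 1.5-fold (134, 52), to 307 at an adjusted p of 0.01 (127, 180) and to 573 by rank sums (255, 318). Of 44 named genes that passed, 26 passed without any 1 array, 27 were lost with 6 marker scores, 23 with the title number as a block, 18 with CGVHD 1 to 10, 17 with CGVHD 11 to 26, 16 with the glucocorticoid covariate, 15 without ND 2, 14 without ND 7 and at most 12 in any other fit at the same threshold; 0 reversed.

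With the title number as a block over 10 pairs, 203 genes passed (106 higher, 97 lower), partly through fewer arrays. Deviations within these pairs correlated at a median r of -0.058 (from -0.21 to 0.37). Arrays of different numbers were not compared in this way, so these values cannot settle whether the numbers pair people. In that blocked fit camera reversed 3 lists: inflammatory cytokines and NF-kB targets (adjusted p = 0.805), immediate-early genes (0.0495) and B cell markers (0.0012). CGVHD 1 to 10 alone reversed the first (0.774) and B cell markers (0.00091), and leaving out high T cell scores reversed T cell markers (0.0181). That last reversal is partly built in, since the arrays left out were chosen by the same T cell score (21 CGVHD against 6 ND kept).

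Lists called by camera were 7 with the 50% filter, 6 with 6 marker scores, 7 with the glucocorticoid covariate and 0 with an estimated correlation, where adjusted p was 0.378 for type I interferon, 0.0690 for interferon-gamma, 0.0690 for pattern receptors, 0.378 for glucocorticoid and 0.373 for platelet lists. Score differences passing were 4 with CGVHD 1 to 10 and 2 with the glucocorticoid covariate. The glucocorticoid score passed with the median of probe sets (0.584), without the arrays apart (0.550) and with CGVHD 11 to 26 (0.590), and was lowest with 6 marker scores (0.299, p = 0.338). The type I score passed with 6 marker scores (0.552), and over its 11 alternatives ranged from 0.279 with CGVHD 1 to 10 (p = 0.194) to 0.580 with high T cell scores left out (p = 0.127). Platelet markers missed with high T cell scores left out (0.474), with CGVHD 1 to 10 (0.373) and with the glucocorticoid covariate (0.511). Alarmins missed with 6 marker scores (0.149), the glucocorticoid covariate (0.235), CGVHD 1 to 10 (0.288) and high T cell scores left out (0.270), scavenger genes also with CGVHD 1 to 10 (0.235), and classical monocyte markers with CGVHD 11 to 26 (0.171), 6 marker scores (0.176) and the glucocorticoid covariate (0.203). The MHC class I score passed with quantile normalization (0.113), centring (0.131), the median of probe sets (0.167), 6 marker scores (0.173), CGVHD 11 to 26 (0.128) and high T cell scores left out (0.183). Other scores that passed were basophil markers with the median of probe sets (-0.173), B cell markers with CGVHD 1 to 10 (-0.438), and NK markers (0.670) and NF-kB targets (0.493) with CGVHD 11 to 26. No gene was in several lists, so leaving out shared genes changed nothing and tests nothing.

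With 1 array left out, genes ranged from 553 to 1536 (higher 229 to 758, lower 324 to 778), lowest without ND 2 and then ND 7 (650). The glucocorticoid score ranged from 0.475 to 0.565 and passed without CGVHD 1, 3, 6, 7, 13, 18 or 21. The type I score ranged from 0.373 to 0.539 and passed without ND 10 or CGVHD 16. The MHC class I score (0.102 to 0.138) passed without ND 5 or 10 or CGVHD 7, 9, 10, 14 or 16, and mature neutrophil markers without ND 1 or 6 (highest 0.260). Lists with a passing spread ranged from 0 to 1, with 0 without ND 1, 2, 4, 5, 6, 8, 9 or 10 or CGVHD 4, 5, 8, 9, 10, 11, 15, 17, 19, 22, 24 or 25. Correlated pairs ranged from 1 to 4. Signal over background limits what dim genes can show, and the lowest 25% were not tested.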

Other observations

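The lists of heat shock, complement, GIMAP and transforming growth factor beta genes were chosen after some of their members had been seen, so list values are given without those members, adjusted over 5 lists, and genes were named from them after their values were seen.

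Heat shock genes were higher in CGVHD beyond HSPA6, HSPB1 and HSPH1, the members that prompted the list. The other 15 tested, chaperones and co-chaperones of protein folding, were all higher in the CGVHD mean, by 0.50 on the log2 scale (SE 0.12, n = 26 against 10, adjusted permutation p = 0.0113, 22 of 26 arrays above the ND mean). Their score was 9.42 ± 0.55 in CGVHD and 8.92 ± 0.17 in ND. CGVHD arrays thus differed widely in it, and this spread was not tested. AHSA1 (1.34-fold, adjusted p = 0.0091), STIP1 (1.26-fold, p = 0.0190), DNAJA1 (1.35-fold, p = 0.0335) and HSPE1 (1.44-fold, p = 0.0391) rose. HSPA1B, HSP90AA1 and HSPD1 of this set are also in the alarmin list, so the lists are not independent. Complement genes, whose products tag targets for uptake, scored 0.17 higher in 12 tested genes (SE 0.06, p = 0.0101, 23 of 26), with C1QC (1.45-fold, p = 0.0386) the 1 that rose beyond C2 (1.99-fold, p = 0.00078), the anaphylatoxin receptor C3AR1 (2.31-fold, p = 0.0046) and SERPING1.

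GIMAP genes, which encode GTPases of lymphocyte survival, were higher together. GIMAP5 (2.36-fold, adjusted p = 0.0091), GIMAP4 (1.88-fold, p = 0.0232) and GIMAP8 (1.86-fold, p = 0.0280) prompted the list, and the other 4 scored 0.55 higher (SE 0.18, p = 0.0101, 24 of 26), with GIMAP6 (1.74-fold, p = 0.0159) and GIMAP1 (1.26-fold, p = 0.0495) rising. For transforming growth factor beta signalling, the inhibitors SMAD7 and SMAD6 (-0.71, p = 0.0021) fell. The other 8 tested feedback and target genes scored -0.12 (SE 0.12, p = 0.201, 19 of 26 arrays below the ND mean), which did not pass, with 6 of 8 lower and SKI, a repressor of the pathway, falling by 0.34 (p = 0.0386). A wider shift in that pathway was neither shown nor excluded.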
